A study of Homo sapiens with 8 samples.

How the data were processed

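Total RNA from 8 samples of THP-1 macrophages was amplified from 10 ng by reverse transcription and in vitro transcription with a 3' IVT Pico kit. Then 3 µg of labelled cDNA was hybridized to Affymetrix Clariom S human arrays, per the labels' protocols. The values used are the authors' deposited log2 expression values, 1 per probe set and array. They were made with RMA (background correction, quantile normalization and probe summary) in Transcriptome Analysis Console 4.0, per the submitters' processing notes, which give no settings; the genome build is not given in the sources used here. RMA with quantile normalization forces arrays toward one distribution, so a shift of all genes together cannot be seen. Between 330 and 424 values per array lie above 16, the log2 ceiling of a 16-bit scan, up to 18.8, so the exact width of the scale is not settled; differences are therefore given in deposited log2 units and not as linear folds.

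Of 24351 entries, 2903 array controls were left out and 21448 probe sets tested without an intensity filter. Gene names come from the platform annotation, updated through Entrez identifiers against a RefSeq gene table, which changed 0 symbols: 17709 probe sets have 1 symbol (17687 distinct), 0 have several and 3739 have none. A gene with several probe sets was represented in the lists by the one with the highest mean over all arrays. No probe set and no entry of the gene table was named AC136475.5.

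Samples were grouped by title, with which the characteristics and the treatment protocols match: 3 M2 scrambled, 3 M2 silenced, 1 M1 control and 1 M2 control. The free-text description of each of the 2 control arrays names the other polarization; the titles were followed. Replicate numbers come from the titles. Deviations from the group means of same-numbered scrambled and silenced arrays correlated across genes at 0.631, 0.245 and 0.433, all over the limit of 0.1 set in advance, so the numbers were taken to pair the samples. Scrambled replicate 3 and silenced replicate 2 correlated at 0.227, close to the value of the second pair, and no label says what the pairs share. At most 2 probe sets had identical values on any pair of arrays.

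Silenced and scrambled arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. The main design, fixed beforehand, had no block, and the replicate number was a block in an alternative. The main design thus leaves out the pairing. Its SEs and its ranking of genes are given for silencing unless the block is named. Scrambled cells were compared with the M2 control in a fit of all 8 arrays with 4 group means. This treats arrays of the same number as independent, so a fit in which they share a correlation (duplicateCorrelation) was added after the data were seen. Camera takes no such correlation, so its list tests leave out the pairing. Fry does take it and was also run with it. The M1 and M2 control arrays, 1 each, were compared as differences only. Lists were 36 sets of 682 genes, of which 615 were measured; TNF, for example, had no named probe set, and 17 of 33 ribosomal proteins were measured. They were tested with camera (preset correlation 0.01, and estimated), which sets a list against other genes, and with fry, which asks whether its genes move one way on balance. Random lists (10000) were matched in 20 bins of expression. Values per array were compared with exact permutation tests, two-sided.

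The groups, designs, lists, alternatives and the rule for named genes were fixed before the data were examined; the list tests of scrambled cells against the M2 control were chosen after seeing the data. Named genes are, for silencing, up to 12 per direction that passed, otherwise the 6 per direction with the smallest unadjusted p, the IFITM family, and from each list described up to 4 members that passed or else the 2 with the smallest p; for the other comparisons, the 10 largest differences per direction with the higher group above the median level, and up to 4 per list described. For scrambled cells against the M2 control, list members that passed were taken first, and otherwise the 2 with the smallest p. This departs from the rule set beforehand, which took the largest differences. CXCL8, MMP7 and MMP8 in the silencing comparison were named because the block changed their count, and FABP4 and CCL22 there as genes the rule names for the controls, all after their values were seen.

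The tests were tested on simulated data drawn from the real means and spreads of the 21448 probe sets, with 50 genes at each size. For silenced against scrambled, 30.0% of genes changed by 1 log2 unit and 96.0% of those changed by 2 were called, and 90.0% and 100% with the block; at 0.5 the shares were 0% and 16.0%. For scrambled against the M2 control, 2.00% were called at 1, 76.0% at 2 and 98.0% at 3. False calls were 10 of 123 calls without the block (8.13%), 17 of 170 with it (10.0%) and 6 of 94 for the M2 control (6.38%), above the 5% aimed at. Each came from a single simulated data set. Without the block and for the M2 control the noise was drawn independently per array, with no differences shared by replicate number. Of unchanged simulated genes without the block 4.95% had an unadjusted p under 0.05, against 1.26% of all real probe sets. With the block, whose noise was drawn with exact pairs, these shares were 5.06% and 3.69%. The recovery and false-call shares of all these designs may therefore not hold for the real arrays. Alternatives covered normalization (quantile and median), a filter on dim probe sets, moderation with a trend, array weights, all 8 arrays, thresholds, set definitions and tests, and leaving out each gapmer array.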

Results

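Gene expression was measured on 8 arrays of macrophages derived from THP-1, an established human monocytic leukemia line that becomes macrophage-like under the phorbol ester PMA. All cells had 24 h of PMA. For 6 of the samples a gapmer, an antisense oligonucleotide that directs RNase H to its target RNA, was then delivered by nucleofection. These cells were polarized for 48 h with IL-4 and IL-13 (25 ng/ml each) toward the M2 state, the alternatively activated form of macrophages. In 3 of these samples the gapmers were directed against the long non-coding RNA AC136475.5 (silenced), and in 3 the gapmer was scrambled. The remaining arrays were polarization controls without a gapmer, 1 array each. The M2 control had the same cytokines, and the M1 control had interferon gamma (50 ng/ml) and lipopolysaccharide (15 ng/ml) for 48 h, the classical inflammatory stimulus. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Median log2 values of the tested probe sets ran from 5.85 to 5.98 over the 8 arrays, and positive controls separated from negative controls with an area under the curve of 0.961 to 0.979. The number of arrays limits the precision.

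In the main test, without the replicate block, no macrophage marker and none of the other genes or gene lists examined passed between silenced and scrambled macrophages. With the block none passed over all genes or as a list, but CXCL8, MMP7 and MMP8 passed adjusted over their list alone. FABP4, a fatty acid binding protein and M2 marker, stood at 13.84 ± 0.46 (log2, SD, n = 3) in silenced and 13.78 ± 0.28 in scrambled cells, and the chemokine CCL22 at 7.06 ± 0.58 and 6.99 ± 0.47. CD163, a scavenger receptor, read 0.52 ± 0.24 (SE) log2 units higher after silencing and the eotaxin CCL26 0.36 ± 0.24, neither of which passed. The interferon-induced genes MX1 and ISG15 differed by 0.48 ± 0.24 and 0.45 ± 0.23, again without passing. On all 6 gapmer arrays CD163, CCL26, MX1 and ISG15 read within the negative controls (at or below the 95th percentile of the array). CCL22 did on 5 of the 6, so the values of these genes may be background. This is the comparison the study was designed around, the effect of silencing AC136475.5 on M2-polarized cells. None of the probe sets was named AC136475.5 in the array annotation, so the fall of the target itself could not be checked and nothing stands in for it.

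Over 21448 probe sets, limma called 0 higher and 0 lower in silenced than in scrambled cells at an adjusted p under 0.05; the smallest adjusted p was 1.000. At an unadjusted p under 0.05 there were 105 higher and 165 lower, 1.26% of all against 5% by chance. With the replicate number as a block the calls remained 0 and 0, and the unadjusted counts were 361 and 430 (3.69%). No difference reached 1 log2 unit, the SD of the differences was 0.21, and the median 95% interval of a gene was ± 0.53 (± 0.42 with the block). All 3 silenced values lay above or below all 3 scrambled values for 1162 probe sets, 5.42% where chance gives 10% if the 6 arrays are exchangeable. The replicate numbers pair the arrays, and differences shared within pairs make such separation rarer, so the 10% is no exact reference here.

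The genes with the smallest unadjusted p, none of which passed, were mostly dim: of the 12, only CCDC86 averaged above 7.83, the highest 95th percentile of negative controls on the gapmer arrays. Among those reading higher after silencing were the bitter taste receptor TAS2R46 (0.92 ± 0.24 SE), ZNF558 (0.98 ± 0.28) and ARL6, a small GTPase of the cilium (0.87 ± 0.25). Also higher were TMSB15A, a thymosin beta (0.74 ± 0.20), the G protein-coupled receptor kinase GRK6 (0.69 ± 0.19) and CCDC86 (0.65 ± 0.19). Among those reading lower were RAD51B, a recombination repair gene (-0.94 ± 0.27), GALNTL5 (-0.84 ± 0.21) and the peptidase TRHDE (-0.84 ± 0.21). Also lower were the cytokine IL20 (-0.79 ± 0.22), the ATP-gated channel P2RX2 (-0.76 ± 0.20) and ZNF30 (-0.60 ± 0.17). The 5 measured IFITM genes, a family of antiviral membrane proteins with members induced by interferon, differed by 0.12 ± 0.41 (IFITM1), 0.08 ± 0.27 (IFITM2), 0.20 ± 0.35 (IFITM3), 0.09 ± 0.19 (IFITM5) and 0.10 ± 0.39 (IFITM10), all within the spread between replicates. IFITM5 and IFITM10 read within the negative controls on all 6 gapmer arrays and IFITM1 on 3 of them.

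By gene list, 0 of the 36 lists passed (camera, smallest adjusted p 0.292), and 0 of their 615 measured genes passed either over all genes or adjusted over the list alone. The lists nearest the threshold included interferon gamma response (27 genes, mean difference 0.11), represented by GBP2 (0.45 ± 0.19) and FCGR1A (0.39 ± 0.20). They also included dendritic cell markers (15 genes, -0.16), represented by CLEC9A (-0.38 ± 0.20) and FCER1A (-0.34 ± 0.20). The 24 M2 markers averaged 0.089 higher and the 37 type I interferon response genes 0.091 higher (adjusted p = 0.382 for each). The 24 M1 markers averaged -0.0072, with a camera direction of up, and included FCGR1A and CD38 (-0.40 ± 0.32). MHC class II presentation genes such as HLA-DRA (-0.26 ± 0.19) and HLA-DPA1 (-0.25 ± 0.19) averaged -0.056 (adjusted p = 0.621). Undifferentiated THP-1 and myeloid progenitor markers, with HGF (-0.56 ± 0.17) and PRTN3 (-0.29 ± 0.23), averaged -0.13 (adjusted p = 0.382). NF-kB targets had a mean of 0.076 and a median of -0.015, with TRAF1 at 0.60 ± 0.23 and CXCL3 at 0.49 ± 0.24. With the block, 3 genes passed adjusted over the list alone and 0 over all genes. In the NF-kB list this was CXCL8, a neutrophil chemokine (0.97 ± 0.23, adjusted p = 0.0329). In the matrix list these were the metalloproteinases MMP8 (0.75 ± 0.19) and MMP7 (-0.88 ± 0.24), each with an adjusted p of 0.0354. The list members named here, except TRAF1, CXCL8, MMP7 and MMP8, read within the negative controls on all 6 gapmer arrays. CXCL8 did on 3 of the 6 and MMP7 on 4, so their differences may be partly background, while TRAF1 and MMP8 did on 0. Leaving out any 1 array brought between 1 and 6 lists past the threshold, with G2/M genes at -0.54 without scrambled replicate 1 and at 0.43 without silenced replicate 1. With an estimated correlation 0 of these lists passed (smallest adjusted p = 0.787 over the 6 fits). Leaving out 1 array also unbalances the replicate numbers, on which 24 of 28 G2/M genes differ.

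The design text adds the polarization controls as a comparison, so each gapmer array was placed between them. Probe sets at least 1 log2 unit higher on the M1 than on the M2 control array (1518 named probe sets) averaged 0.013 higher in silenced cells, and those at least 1 lower (1293) averaged -0.0091 (camera, adjusted p = 0.929 for each). The mean of the M1-high minus that of the M2-high set was -0.29 ± 0.092 (SD, n = 3) in silenced and -0.32 ± 0.14 in scrambled cells (two-sided exact permutation p = 0.8, adjusted 0.9), against 2.28 on the M1 and -0.92 on the M2 control array. These sets were chosen on the control arrays, whose own values are therefore extreme. The preset M2 markers averaged 5.89 ± 0.019 (SD, n = 3) in silenced and 5.80 ± 0.018 in scrambled cells, higher in 3 of 3 same-numbered pairs and without overlap between the groups (exact permutation p = 0.1, the smallest 3 against 3 arrays allow; adjusted 0.4 over 4 comparisons). The preset M1 markers averaged 5.85 ± 0.17 and 5.86 ± 0.090 (SD, n = 3; exact permutation p = 0.9). On every gapmer array both marker averages lay below the 95th percentile of its negative controls (7.01 to 7.83), so part of them may be background. Across genes, which are not independent replicates, the silencing difference and the M1 minus M2 difference had a Pearson r of 0.0352 and a Spearman rho of 0.0188, and 7 of the 10 regroupings of the 6 gapmer arrays gave an r as large.

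**Figure D1:**
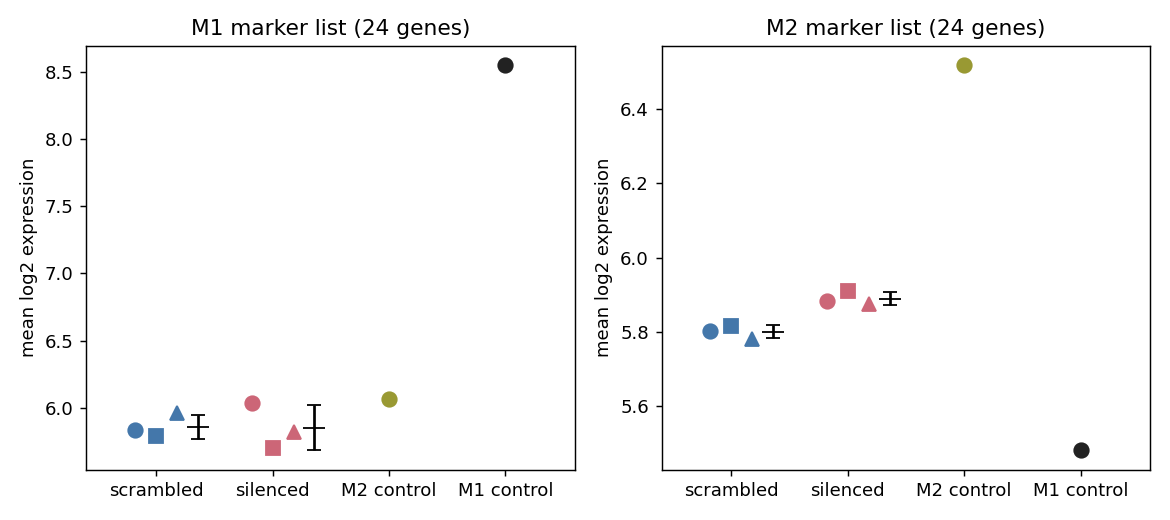
Mean log2 expression of the preset M1 markers (left) and M2 markers (right) on each array, 1 point per array, with circles, squares and triangles for replicates 1, 2 and 3 and bars for mean ± SD of 3 arrays. M1 markers average 8.55 on the M1 control array and 6.07 on the M2 control array, and M2 markers average 6.52 on the M2 control array against 5.80 and 5.89 in scrambled and silenced cells. On every gapmer array both averages lie below the 95th percentile of its single negative controls (7.01 to 7.83) and above their median (3.90 to 4.25).

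The M1 control array differed from the M2 control array in many interferon-induced and inflammatory genes and in some M2 markers. Interferon-induced genes were far higher on the M1 array, with SERPING1, the C1 inhibitor, higher by 9.02 log2 units (11.99 against 2.97). IFI44L was higher by 8.13, the guanylate binding protein GBP1 by 8.03, MX1 by 7.27, CMPK2 by 6.99 and IFI44 by 6.44. TNFAIP6, an inflammation-induced hyaluronan binding protein, was 8.21 higher, the DNA sensor AIM2 6.73 and the chemokine receptor CCR7 6.51. NCF1, an NADPH oxidase subunit that read 6.61 higher, has near-identical pseudogenes and is uncertain. FABP4 was 9.22 lower on the M1 array (5.82 against 15.03), the retinoic acid-forming enzyme ALDH1A2 5.74, S100A4 5.59, CCL22 5.28 and AK5 5.02. Also lower were the aquaglyceroporin AQP9 (by 4.87), the leukotriene receptor CYSLTR1 (4.66), ANXA1 (4.56), LTBP1 (4.40) and the transglutaminase TGM2, an M2 marker (4.26). On the M2 control array all 10 genes named as higher read within the negative controls (at or below their 95th percentile, 7.47). On the M1 control array 8 of the 10 named as lower did (8.23), all but ANXA1 and TGM2. The sizes and order of these differences therefore depend on background. There is 1 array per state, so they have no replicate check and no p-value. In all, 1955 probe sets were at least 1 log2 unit higher and 1533 at least 1 lower, with 415 and 197 at 2 or more, around a median of -0.03.

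Gene lists were described by the percentile of their median among 10000 random lists of the same size and mean expression. At the 100th percentile stood type I interferon response (median 3.98, with 36 of 37 genes at least 1 higher). So did MHC class II presentation (4.38, 10 of 12), with HLA-DRA at 5.71, HLA-DMA at 5.69, HLA-DPA1 at 5.16 and their transactivator CIITA at 4.77. M1 markers (2.64, 16 of 24) were there with GBP5 at 6.43, the tryptophan-degrading enzyme IDO1 at 5.88 and the transcription factor IRF1 at 5.34, as was interferon gamma response (2.63, 20 of 27). The same held for the IFITM family (2.29, 4 of 5: IFITM1 at 4.30, IFITM3 at 3.80, IFITM10 at 2.29 and IFITM2 at 2.09, with IFITM5 at -0.036). MHC class I presentation (1.65, with NLRC5 at 4.16 and TAP1 at 3.15) and NF-kB targets (1.16, with CXCL8 at 4.54, CCL20 at 3.05 and IL1B at 3.01) followed. Inflammasome genes (1.02), complement components (0.90, with C2 at 5.85 and CFB at 2.82) and nucleic acid sensors (0.75, with IFIH1 at 3.98 and RIGI at 3.73) were also at the 100th percentile. Integrated stress response genes (0.60, percentile 99.7) and NRF2 targets (0.56, 98.8) lay above the middle 95% of random lists as well. Cell division genes were lower on the M1 array: the G2/M list had a median of -1.75 (percentile 0, 22 of 28 genes at least 1 lower), with CDK1 at -3.03, CCNA2 at -2.99, PLK1 at -2.67 and ANLN at -2.66. M2 markers stood at -0.43 (percentile 0.2), with 6 of 24 at least 1 lower and 2 at least 1 higher, and S phase genes at -0.51 (0.23, 8 of 25 at least 1 lower). Ribosomal proteins stood at -0.66 (0.63, with RPL6 at -1.55 and RPL14 at -1.36) and cholesterol biosynthesis genes at -0.47 (1.84, with DHCR7 at -3.39 and SC5D at -1.52). The percentiles do not take in the spread between arrays of a group. G2/M genes averaged 7.29, 9.07 and 8.55 on the 3 scrambled arrays, against 5.51 on the M1 and 7.11 on the M2 control. In the same order S phase genes averaged 7.94, 9.09 and 8.77, against 6.57 and 7.21. Cholesterol genes averaged 11.12, 10.50 and 9.85, against 9.71 and 10.30, and NRF2 targets 11.01, 10.04 and 9.87, against 10.24 and 9.62. In each list the scrambled arrays lie farther apart than the controls. With the mean of the 3 scrambled arrays as the M2 reference, AQP9 turned to 1.66, IL1B to -0.39 and IFITM5 to 0.59, and CCL22 shrank to -0.70 and ALDH1A2 to -0.72. Of the 49 genes named in this comparison, 35 read within the negative controls on the array where they were lower, among them the MHC class II genes given, and 3 (CDK1, CFB and IFITM5) did on both arrays, so their sizes and order depend on background.

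**Figure D2:**
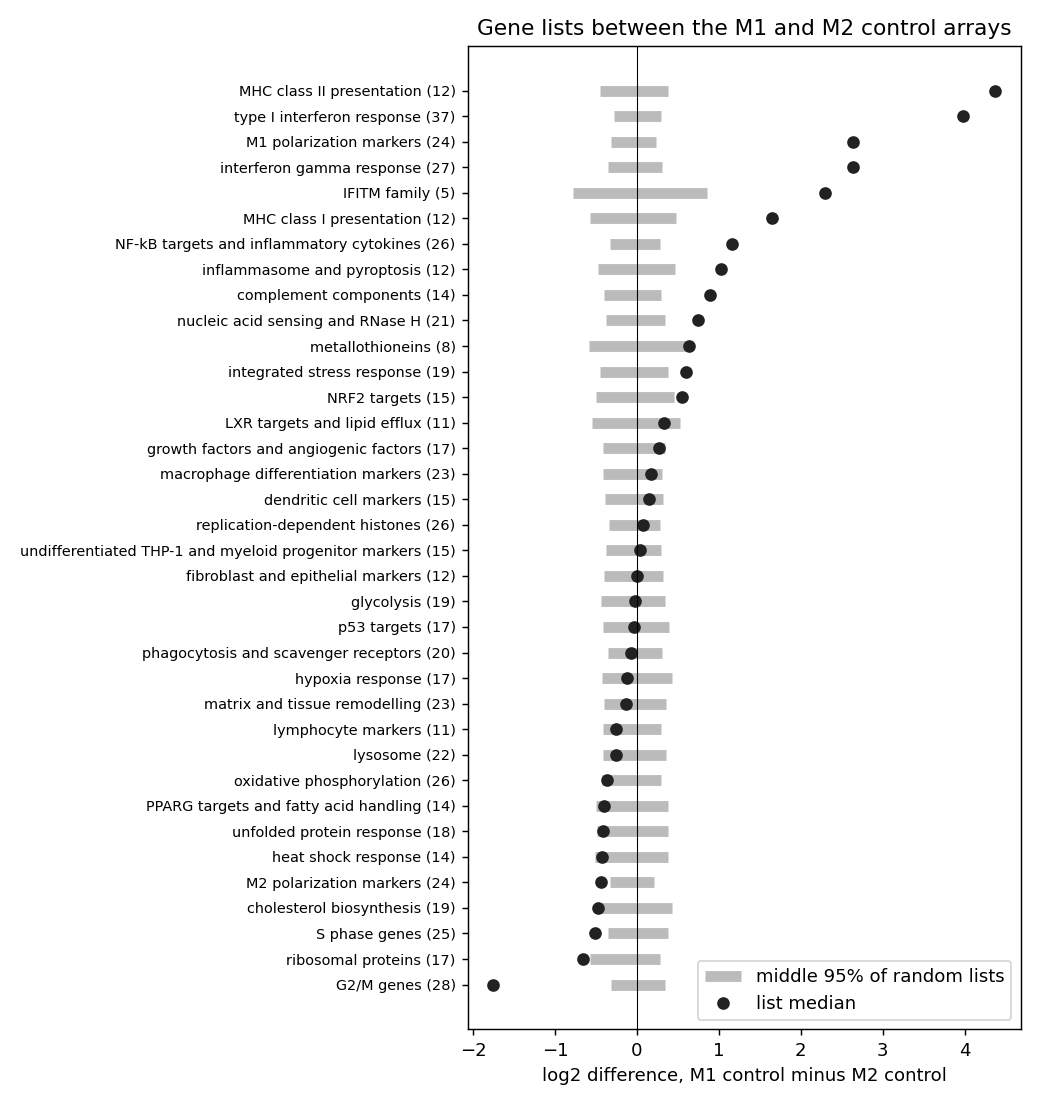
Median log2 difference of each gene list between the M1 and the M2 control array (points, measured genes in brackets), with the middle 95% of the medians of 10000 random lists of the same size and expression (grey bars). MHC class II genes (4.38) and type I interferon response genes (3.98) lie farthest to the M1 side and G2/M genes (-1.75) farthest to the M2 side.

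Nucleofected M2 macrophages that received the scrambled gapmer differed widely from the M2 control array. Higher in the scrambled cells were the Notch ligand JAG1 (6.23 ± 0.59 SE log2 units), the intermediate filament INA (5.86 ± 0.29) and the tropomyosin TPM2 (5.53 ± 0.25). So were the secreted glycoprotein STC1 (5.46 ± 1.07), the urokinase plasminogen activator PLAU (5.46 ± 0.47) and the amino acid transporter SLC38A5 (5.30 ± 0.38). ERRFI1 (5.27 ± 0.43), the ubiquitin ligase NEDD4L (4.88 ± 0.46), the growth factor NRG1 (4.73 ± 0.73) and the matrix protein TGFBI (4.67 ± 0.26) were higher as well. Lower were IL1RN, the interleukin-1 receptor antagonist (-7.48 ± 0.52), AQP9 (-6.53 ± 0.38), and the retinoic acid binding protein CRABP2 (-5.94 ± 1.12). Lower too were COL11A2 (-5.75 ± 0.41), MMP7 (-5.58 ± 1.21), FA2H (-5.19 ± 0.95), ALDH1A2 (-5.02 ± 0.47), PHGDH, the first enzyme of serine synthesis (-5.02 ± 0.33), the chitotriosidase CHIT1 (-4.87 ± 0.29) and the interferon-induced IFI6 (-4.83 ± 0.50). Of the 10 genes named as higher, 9 read within the negative controls on the M2 control array (all but TGFBI). Of the 10 named as lower, 7 did in the scrambled cells (all but CRABP2, ALDH1A2 and IFI6), so the sizes and order of these differences depend on background. Limma called 502 probe sets higher and 449 lower. This fit leaves out the pairing of arrays by number. With arrays of the same number sharing an estimated correlation (0.369), an alternative added after the results were seen, it called 566 and 489, 927 of them among the 951. For 14 of the 20 genes named the M1 control array lay nearer the M2 control array than the scrambled cells, and for 6 (TPM2, NRG1, AQP9, COL11A2, MMP7 and ALDH1A2) it did not. Among the 14, IL1RN was 12.34 on the M1 control, 13.61 on the M2 control and 6.13 in scrambled cells, and CHIT1 was 8.32, 8.36 and 3.49. PHGDH was 11.21, 12.10 and 7.09, and JAG1 was 5.38, 5.05 and 11.28.

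In this comparison 28 of the 53 genes named read within the negative controls on the side where they were lower, and 5 (CD209, FCGR1A, IFIT1, ABCG1 and ADAM19) on both sides, so the sizes of their differences depend on background. Some M2 markers were lower in the scrambled cells than on the M2 control array. Of 24, 3 passed: CCL22 (-4.58 ± 0.48), the lipid-sensing receptor PPARG (-3.47 ± 0.30) and the lectin CD209 (-2.30 ± 0.30). Adjusted over the list alone 7 were lower and 1 higher (camera adjusted p = 0.00194; adjusted p = 0.161 with an estimated correlation). Type I interferon response genes were lower in 15 of 37 and higher in 0, among them IFI6, IFIT3 (-3.62 ± 0.43), IFI27 (-2.79 ± 0.47) and IFIT1 (-2.63 ± 0.39). Adjusted over the list alone 24 were lower (adjusted p = 7.77e-12; adjusted p = 0.194 with an estimated correlation). Genes of the list of LXR targets and lipid efflux were lower in 5 of 11, led by ABCG1 (-3.76 ± 0.26), APOE (-3.39 ± 0.44), the desaturase SCD (-3.22 ± 0.41) and APOC1 (-2.98 ± 0.48), and 8 adjusted over the list alone. Integrated stress response genes were lower in 8 of 19, led by PHGDH, PSAT1 (-3.91 ± 0.32), ASNS (-3.12 ± 0.33) and CHAC1 (-2.76 ± 0.48), likewise 8 adjusted over the list alone. For LXR targets and stress genes camera gave adjusted p-values of 1.33e-05 and 4.38e-07, and 0.130 for each with an estimated correlation. That correlation was -0.035 for M2 markers, -0.026 for LXR targets and 0.017 for stress genes, near or below the preset 0.01. The larger p of these lists therefore does not show that their genes move together strongly. With fry, M2 markers (adjusted p = 0.000614), LXR targets and stress genes (0.00178 for each) passed. For type I interferon genes the estimate was higher, 0.147. Lysosome genes were lower in 3 of 22, LIPA (-2.10 ± 0.30), ATP6V1H (-1.99 ± 0.35) and ASAH1 (-1.87 ± 0.27), and macrophage differentiation markers in 4 of 23 with CD36 higher (2.70 ± 0.44). Adjusted over the list alone these were 3 lower for lysosome genes, and 5 lower and 1 higher for differentiation markers (adjusted p = 0.00194 and 0.0260; adjusted p = 0.659 for each with an estimated correlation).

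Glycolysis genes were higher in the scrambled cells in 4 of 19, the glucose transporter SLC2A1 (4.14 ± 0.42), LDHA (2.06 ± 0.30), ENO1 (1.31 ± 0.25) and PFKP (1.26 ± 0.25). Adjusted over the list alone 6 were higher (camera adjusted p = 0.000198; adjusted p = 0.436 with an estimated correlation). Matrix and remodelling genes were higher in 4 of 23 and lower in 1 (MMP7), with PLAU, TGFBI and the metalloproteinase ADAM19 (2.76 ± 0.37) among the higher. Adjusted over the list alone 8 were higher and 1 lower. Camera gave this list an adjusted p of 7.00e-05, and 0.159 with an estimated correlation, which was 0.015 and so near the preset 0.01. S phase genes had a median of 1.39, with 1 of 25 passing (RFC2, 2.27 ± 0.49) and 7 adjusted over the list alone. G2/M genes had a median of 1.32 with 0 of 28 passing, CCNB1 at 2.81 ± 0.85 and ANLN at 2.31 ± 0.79. S phase and G2/M genes passed as lists (adjusted p = 5.08e-08 and 0.000387; adjusted p = 0.659 and 0.778 with an estimated correlation). The G2/M list averaged 7.29, 9.07 and 8.55 on scrambled arrays 1, 2 and 3 and 7.11 on the M2 control array. NRF2 targets, with NQO1 at 1.98 ± 0.78 and GSR at 1.03 ± 0.39, and ribosomal proteins, with RPL19 at 0.95 ± 0.25 and RPL7 at 0.53 ± 0.24, passed as lists with 0 members passing (adjusted p = 0.0119 and 0.0260; adjusted p = 0.778 and 0.659 with an estimated correlation). M1 markers did not pass as a list (adjusted p = 0.306), with IL1B higher (3.41 ± 0.66) and CCL5 (-3.52 ± 0.70), FCGR1A (-2.21 ± 0.28) and SLAMF7 (-1.86 ± 0.40) lower.

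This comparison rests on 1 array without a gapmer, which the fit assumes to vary like the gapmer arrays, and the labels do not say whether it was cultured and processed together with them. Without scrambled replicate 2 the counts were 125 higher and 155 lower, 271 of them among the 951 found with all arrays. There STC1 (adjusted p = 0.0951), CCL5 (0.0957), IL1B (0.0688), SLAMF7 (0.1005), CHAC1 (0.0729), ENO1 (0.0856), PFKP (0.0892), ATP6V1H (0.0663) and RFC2 (0.110) no longer passed. Their differences stayed of similar size: STC1 5.35, CCL5 -3.46, IL1B 3.63, SLAMF7 -1.67, CHAC1 -2.70, ENO1 1.25, PFKP 1.25, ATP6V1H -2.02 and RFC2 2.07. Without scrambled replicate 1, PFKP (0.0567) and RFC2 (0.0616) lost the call and CCNB1 (0.0473) and ANLN (0.0331) gained it. Without scrambled replicate 3, MMP7 (0.0656), IL1B (0.0530) and SLAMF7 (0.0596) lost it. NRF2 targets lost their call as a list without scrambled replicate 1 (adjusted p = 0.140), and their mean difference fell from 0.69 to 0.34. Interferon gamma response (0.0339) and histones (0.00328) gained a call there, as cholesterol biosynthesis did without replicate 3 (0.0267). With an estimated correlation none of these 4 passed (adjusted p = 0.799, 0.566, 0.454 and 0.792 with an estimated correlation).

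**Figure D3:**
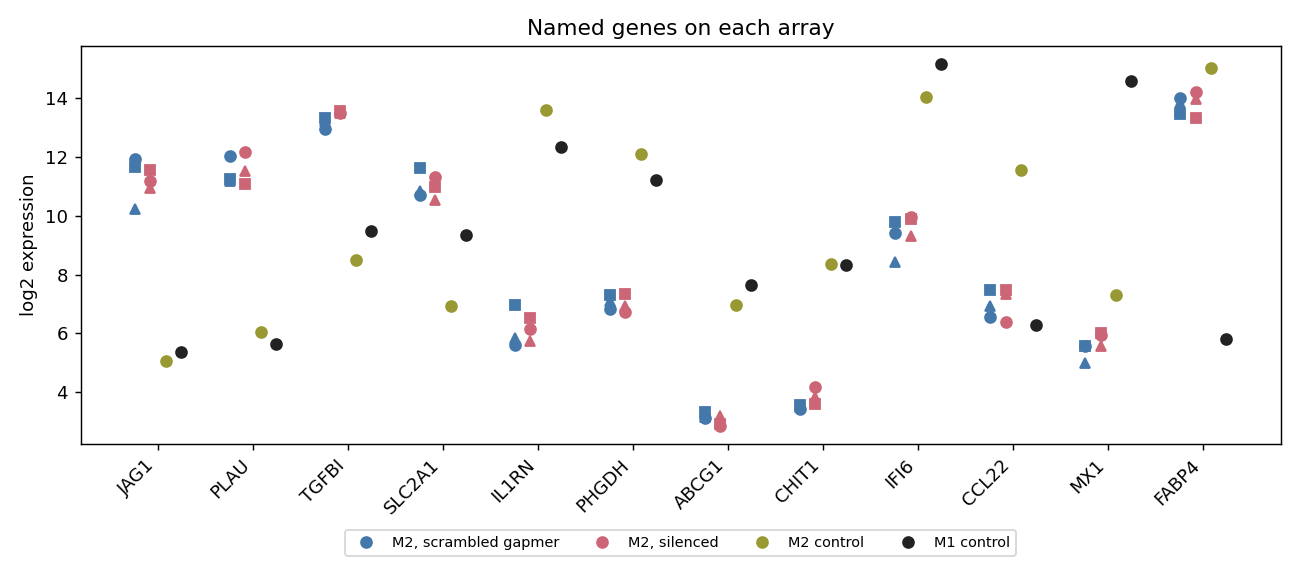
Log2 expression of 12 named genes on each array, 1 point per array, coloured by group, with circles, squares and triangles for replicates 1, 2 and 3. For IL1RN the scrambled mean is 6.13 against 13.61 on the M2 control array, and for FABP4 the M1 control array stands at 5.82.

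**Figure D4:**
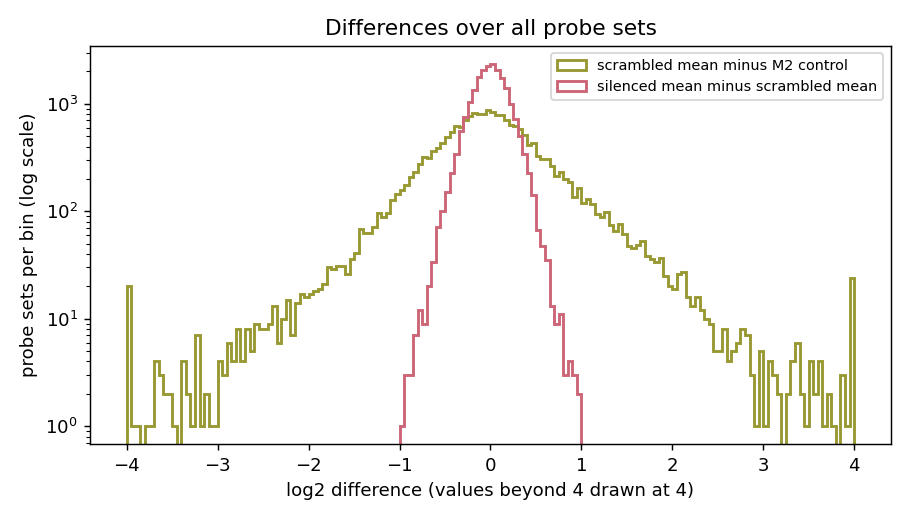
Number of probe sets (log axis) by log2 difference, for the silenced mean minus the scrambled mean and for the scrambled mean minus the single M2 control array. No difference of silenced and scrambled means reaches 1, whereas 2928 probe sets differ by at least 1 between scrambled cells and the M2 control array, a difference that also carries the noise of a single array.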

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

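The list tests of scrambled cells against the M2 control, their alternatives and the fit with a correlation shared by arrays of the same number were chosen after the results were seen. The count of 0 probe sets between silenced and scrambled cells held under every alternative run, except that an unadjusted p under 0.05 with a difference of 1.5-fold on the log2 scale took in 112 (0 at 2-fold). The block changed no other call than those given in the report. With array weights 1 list passed, cholesterol biosynthesis (mean difference -0.23, adjusted p = 0.0499; adjusted p = 0.939 with an estimated correlation; smallest adjusted p over the other alternatives with all arrays 0.183 to 0.966), and leaving out 1 array brought 1 to 6 lists and 0 to 1 of the M1-high and M2-high sets past the threshold. The set past it was M2-high without scrambled replicate 3 (mean -0.064, adjusted p = 0.0167). Without 1 array, S phase genes ranged from -0.28 (without scrambled replicate 1) to 0.36, and G2/M genes from -0.54 to 0.43 (without silenced replicate 1; 0.35 without scrambled replicate 2). Lysosome genes ranged from -0.18 (without silenced replicate 1) to 0.13. The estimated correlation was 0.844 for G2/M, 0.661 for S phase and 0.178 for lysosome genes, and the preset one 0.01. The cause was not tested.

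The M1-high minus M2-high difference between silenced and scrambled cells ranged from -0.060 to 0.067 without 1 array and from 0.016 to 0.079 under the other settings, and r across genes from -0.047 to 0.080 and from 0.031 to 0.071. Between the control arrays the counts of probe sets at least 1 higher and lower ranged from 1431 to 2251 and from 1103 to 2072, within 1.5 times the 1955 and 1533 of the report. Of the named genes, AQP9 turned to 1.66, IFITM5 to 0.59 and IL1B to -0.39 against the scrambled mean, and 31 of 136 values moved by more than the replicate SD without turning. Scrambled against M2 control, leaving out 1 array gave 125 to 527 higher and 155 to 418 lower; the low values are those without scrambled replicate 2, and the cause was not tested. With all 3 scrambled arrays no named gene lost or gained its call in 259 values, but ribosomal proteins lost theirs as a list after renewed quantile normalization (adjusted p = 0.0981), and ribosomal proteins, macrophage differentiation markers (0.205 for each) and NRF2 targets (0.112) on bright probe sets only. With an estimated correlation 0 lists passed, and with fry M2 markers (0.000614), type I interferon response (0.0147), LXR targets and integrated stress response (0.00178 for each) and matrix genes (0.0103) did. Fry with the correlation shared by arrays of the same number called the same 5 lists. The adjusted p was 0.000282 for M2 markers, 0.00194 for integrated stress response and 0.00258 for LXR targets. It was 0.0136 each for type I interferon response and matrix genes.

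The planned values of the target RNA itself could not be given, since no probe set is named for it. Signal over background limits the dim genes: 30.1% to 39.4% of probe sets lay above the 95th percentile of negative controls of their array.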

Other observations

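The tests here, and the genes named for replicate numbers, were chosen after the results were seen, except the share of bright genes in the comparison with the M2 control and the counts over other splits of the samples. The replicate number separated the gapmer arrays more than silencing did. In the fit with the block, 1395 probe sets differed between replicate numbers at an adjusted p under 0.05, against 0 between silenced and scrambled cells. Cell division genes led: 24 of 28 G2/M genes and 14 of 25 S phase genes differed, against 6.03% and 6.09% of the other genes (Fisher's exact test, adjusted p = 4.03e-24 and 4.39e-10 over 36 lists). TOP2A, a topoisomerase of dividing cells, averaged 8.60 on both arrays numbered 1, 11.05 on those numbered 2 and 10.66 on those numbered 3, and the proliferation marker MKI67 averaged 9.74, 12.10 and 11.91. DHCR7, the last enzyme of cholesterol synthesis, averaged 11.04, 8.49 and 7.96, and the cystine transporter SLC7A11, an NRF2 target, 14.44, 10.83 and 11.14. In their lists 9 of 19 cholesterol biosynthesis genes and 7 of 15 NRF2 targets differed (adjusted p = 7.77e-06 and 9.84e-05), as did 9 of 23 matrix genes (4.12e-05), 6 of 22 lysosome genes (0.0102) and 4 of 12 inflammasome genes (0.0244). Among the matrix genes the macrophage elastase MMP12 stood at 10.72, 7.93 and 7.32, MMP7 at 5.60, 8.52 and 7.02 and fibronectin (FN1) at 8.03, 9.70 and 10.66. Genes are not independent replicates, so these p-values describe these arrays.

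Whether the cultures differed in how many cells were dividing stays open: the 85.7% of G2/M genes that differed between replicate numbers are the observation itself, not a separate test. A difference in array background as the whole cause is argued against by the 52.97% of the 1395 probe sets whose mean lay above the 95th percentile of negative controls, against 31.2% of the others. What the numbers stand for (a culture, a day or an array batch) is not in the labels, and no biological explanation from the design was tested.

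The 951 probe sets that differed between scrambled cells and the M2 control array could come from that array alone. The M1 control, a separate sample also without a gapmer, lay nearer the M2 control than the scrambled mean for 67.9% of them (49.9% of the other probe sets). This argues against a deviation of the M2 control array alone for many of them. It cannot tell for genes that the M1 stimulus itself raises, such as the interferon-induced IFI6 (15.17 on the M1 control, 14.04 on the M2 control, 9.21 in scrambled cells). Of 37 type I interferon response genes 15 were among those called. An exchange of the control arrays is argued against by the M1 markers, higher by a median of 2.64 on the array titled M1. For 38.4% of the called probe sets both levels lay above 8.23, the highest 95th percentile of negative controls. This argues against array background as the cause of all the calls. The other called probe sets had a level at or below that limit, so background stays open for those. Nucleofection, the gapmer itself and a separate culture or processing batch of the controls all remain open, since no array separates them.

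The absence of calls after silencing could come from replicate differences that hide it or from weak silencing of the target RNA. With the block, 3.69% of probe sets had an unadjusted p under 0.05, so no excess over the 5% of chance appeared once replicate differences were taken out. The blocked counts varied between splits, as given below, so the 5% is no exact reference here. Most simulated changes of the smallest size were also missed with the block. The share therefore cannot decide whether replicate differences hide changes of moderate or small size, and these stay open. Weak silencing cannot be told apart from a lack of effect, because 0 probe sets were named for the target. Whether any of the 3739 probe sets without a gene symbol measures it is not known. The 10 splits of the 6 gapmer arrays are too few for a share under 0.05: the real split gave 0 calls, 270 probe sets at an unadjusted p under 0.05, 0 lists and 0 of the M1-high and M2-high sets, and the highest of the others 0, 3651, 11 and 2, with all 10 splits at or above the real one in each. The 4 with the highest counts (1540 to 3651) part 1 pair and so place replicate numbers on opposite sides, and among the 4 splits that part all 3 pairs the blocked counts were 791 for the real one and 874, 1110 and 1420 for the others.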
